A study of Homo sapiens with 12 samples.

How the data were processed

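The data are gene expression profiles of 2 human prostate cancer cell lines, 22RV1 and LnCaP, each grown untreated or exposed to 100 µM nicotine tartrate for 24 h. Per the labels, each of the 4 groups holds 3 replicates, so the series has 12 arrays. Per the labels' protocols, RNA was isolated with TRIzol and biotin-labelled cRNA was hybridised to Affymetrix arrays, which makes them single-colour measurements. The labels call the controls untreated and name no vehicle, and nothing says whether replicates came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical.

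The authors deposited a table of log2 expression values for 22277 probe sets on the 12 arrays. The normalization method and the software are not given in the sources used here. The values themselves lay on a log scale, with array medians between 6.61 and 6.71, and the array medians differed by up to 0.10. They were used as deposited, with no filter. The number of arrays limits the precision, and the median standard error of a log2 fold change within a line was 0.11.

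Probe sets were named through the platform annotation. Of the probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 were unlisted and stay unnamed here. Updating symbols through the Entrez identifier changed 0 of them. For the 4310 genes with several probe sets, the probe set with the highest mean over the 12 arrays was used, which left 11963 genes. Probe sets with several symbols or none entered only a fit of all probe sets.

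All 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means, no covariate). The contrasts were nicotine against untreated in 22RV1, the same in LnCaP, the average of both effects, the difference of both effects, and untreated LnCaP against untreated 22RV1. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. Rose, fell, higher and lower in a count of called genes refer to that call. Standard errors (SE) are those of the moderated fit.

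The design, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes, or, with fewer than 20 calls, the smallest p-values up to 20 genes, given as values that did not pass. The rule further took up to 10 genes with the smallest p for the difference of effects, the 6 highest and 6 lowest for the untreated lines, and 2 to 4 members of each reported list, or its called members. CHRNA5, KLK3, CYP1A1, IL6 and CXCL8 were always named, and 2 further genes of the rule are not analysed here. Uncharacterised loci, small RNAs and pseudogenes counted in totals and were passed over for naming.

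The gene lists were tested with camera (preset inter-gene correlation 0.01), which compares a list with the other genes, and adjusted over the 30 lists that had at least 5 measured members. Of 704 listed symbols, 583 were measured. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance to the same side, were run as alternatives. List means of same-numbered arrays were also compared by an exact sign-flip test over the 6 pairs.

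The labels number the replicates alike in every group, and the data were checked for pairing. Within a line, the correlation over genes of the deviations of same-numbered untreated and treated arrays from their group means was 0.465, 0.454 and 0.640 in 22RV1 and 0.371, 0.225 and 0.599 in LnCaP. Every value was above 0.1, so the numbers were taken to pair the arrays, with the labels as the source of the numbers and the data as the source of the pairing. Between arrays of other numbers, r reached 0.270 in 22RV1. In LnCaP, untreated replicate 2 had a higher r with a treated array of another number (0.270) than with treated replicate 2. For number 3, the highest r with another number was -0.438 in 22RV1 and -0.2175 in LnCaP. The data thus set number 3 apart, but did not settle the pairing of numbers 1 and 2 in LnCaP, on which the block also rests. A fit with the replicate number within the line as a block (6 blocks) is given beside the counts, called lists and named genes that it changes. For lists that were not called, its member counts are given only in part. Deviations of same-numbered arrays of different lines also correlated, with a mean r of 0.156 (0.225 for number 3) against -0.074 for other numbers. The arrays of the lines may therefore share differences by number and not be fully independent.

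The fit was tested on simulated data with the measured variances of the 11963 genes, of which 200 were changed in LnCaP only. Without pairing, changes of 0.5, 1 and 2 log2 units were recovered for 61.2%, 89.55% and 98.5% of the changed genes, with 7 false calls among 173, and 0 genes were called in 22RV1. When pairs shared 50% of the variance, a change of 0.5 was recovered for 47.8% without the block and for 70.1% with it, with 0 false calls among 158 and 11 among 186. When pairs shared nothing, the block lowered that recovery to 41.8%, with 8 false calls among 154. In 20 simulations without change, camera called 0 lists, and it called a list shifted by 0.5 in all 20. These simulated genes were independent, so they do not cover lists whose genes vary together. For gene recovery each pair setting was drawn once, with an equal spread on all arrays and nothing shared between lines. The measured arrays numbered 3 held 48.0% of the residual sum of squares, so the recovery and false calls may differ in these data.

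Alternatives were quantile normalization, centring on the array median, leaving out genes below the 40th percentile of mean level, a trended and robust variance model, array weights, all probe sets, the mean over the probe sets of a gene, fits of only the 6 arrays compared, the replicate block, and leaving out each array. Other splits of the arrays were fitted in the same way. Figures were drawn with matplotlib 3.10.9.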

Results

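Expression was measured on 12 arrays, with 3 replicates in each of 4 groups, to compare 22RV1 and LnCaP cells after 24 h in 100 µM nicotine with untreated cells of the same line. 22RV1 and LnCaP are established human prostate cancer cell lines. The series title places the work beside an immune and inflammation signature of prostate tumors from smokers. The lowest correlation between arrays of a group was 0.992, whereas the highest correlation between arrays of different lines was 0.933. A principal component that held 87.8% of the variance separated the lines. The 4 arrays numbered 3 stood apart from the others of their groups and held 48.0% of the residual sum of squares.

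The genes called lower after nicotine in LnCaP included genes of cell division and DNA replication. The kinesin KIF4A fell by 0.78 ± 0.11 on the log2 scale (SE, n = 3 per group, adjusted p = 0.0192), and the survivin gene BIRC5 fell by 0.74 ± 0.12 (adjusted p = 0.0233). The DNA exonuclease EXO1 fell by 0.96 ± 0.19 (adjusted p = 0.0469) and GINS1, a subunit of the replicative helicase, fell by 0.84 ± 0.16 (adjusted p = 0.0394). PLA2G2A, a secreted phospholipase, rose by 1.69 ± 0.23 (adjusted p = 0.0192) and the alpha-tubulin gene TUBA1A rose by 1.35 ± 0.26 (adjusted p = 0.0407). In all, 83 of 11963 genes were called in LnCaP, of which 13 rose and 70 fell.

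The other large falls in LnCaP were those of CADPS2 (log2 fold change -0.96), OIP5 (-0.79), CLEC7A (-0.78), the centriole kinase PLK4 (-0.77), the condensin subunit NCAPG (-0.76) and the checkpoint ATPase TRIP13 (-0.75). LARP6 rose by 0.84, IRS1, an adaptor of insulin signalling, by 0.77, SSBP2 by 0.69, B3GALT4 and FAM13A by 0.58, the histone gene H3C6 by 0.57, WASL by 0.47 and CPE by 0.45. The other probe set of B3GALT4, which was dimmer, moved the opposite way. A fit with the replicate block called 645 genes in LnCaP (253 higher and 392 lower), including all 83. The count was 0 without treated replicate 2 or without untreated replicate 3, 2 without untreated replicate 1 and 27 without treated replicate 1. It was 1 in a fit of the 6 LnCaP arrays alone (1 higher and 0 lower, so none of the falls was called there), 175 with array weights and 143 without the arrays numbered 3.

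Of the 30 measured G2/M genes, all had negative log2 fold changes in LnCaP, and 10 fell: BIRC5, KIF23, BUB1B, CCNA2, TTK, KIF11, NUSAP1, UBE2C, MKI67 and TPX2. CCNA2, which encodes cyclin A, fell by 0.69, MKI67, the gene of the proliferation marker Ki-67, by 0.61 and TPX2 by 0.56. Adjusted over the list alone, 29 fell, and 26 fell with the replicate block. The list median was -0.62 (camera adjusted p = 2.53e-35, and adjusted p = 0.155 with an estimated correlation). Fry gave an adjusted p of 0.00755. The list mean was lower in the treated array of 6 of 6 same-numbered pairs over both lines (exact sign-flip p = 0.03125, the smallest possible, 0.188 after adjustment over the lists). The same p was reached by 4 other lists, namely androgen-induced and androgen-repressed targets, respiratory chain genes and NRF2 oxidative stress genes, the last with a mean change of -0.022.

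Of the 28 measured G1/S and replication genes, all had negative values in LnCaP and only TYMS, which encodes thymidylate synthase, fell (-0.73, adjusted p = 0.0265). Adjusted over the list alone, 23 fell, and 20 fell with the replicate block. The list median was -0.68 (camera adjusted p = 1.16e-22, and adjusted p = 0.278 with an estimated correlation). MCM7, a subunit of the replicative helicase, at -0.75 (adjusted p = 0.0661), and CDC45, another part of that helicase, at -0.99 (adjusted p = 0.0726), did not pass over all genes and were picked after their values were seen.

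**Figure D1:**
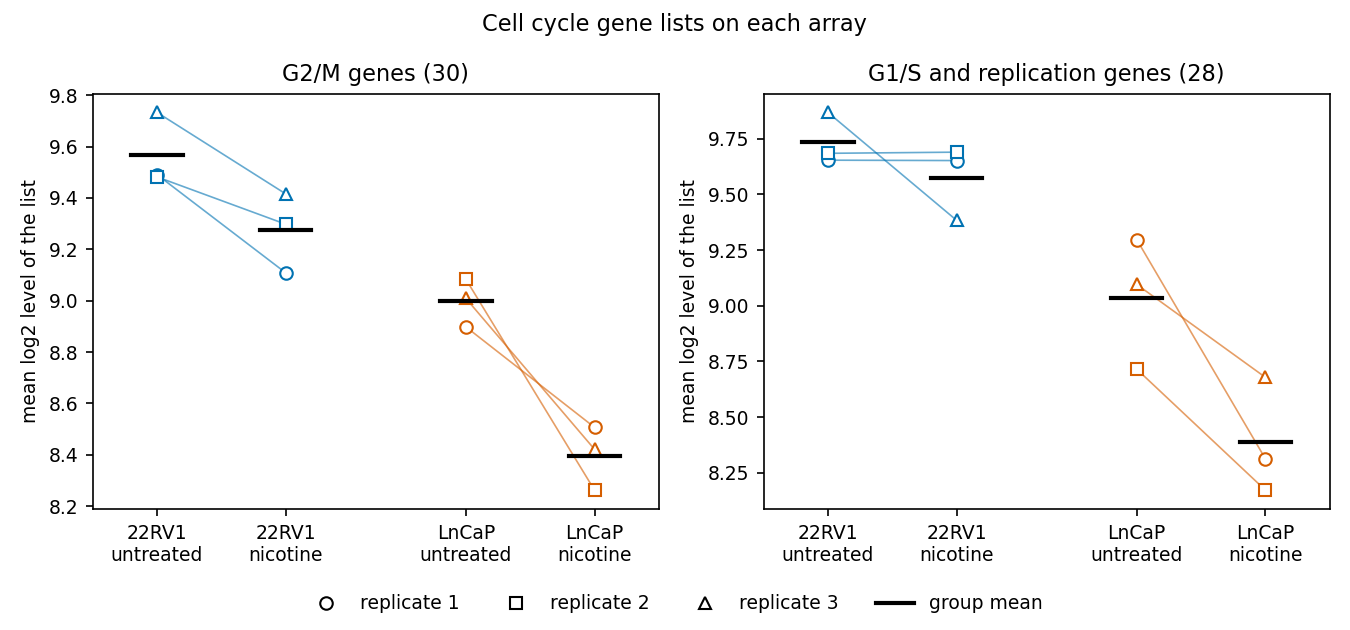
Mean log2 level of the G2/M list (30 genes) and of the G1/S and replication list (28 genes) on each of the 12 arrays, with lines joining same-numbered arrays and black bars at group means. In LnCaP the G2/M mean was 8.997 ± 0.093 untreated and 8.397 ± 0.124 after nicotine (SD, n = 3).

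Androgen targets were called as lists in LnCaP. The 21 androgen-induced targets had a median of -0.20 (camera adjusted p = 0.00400, and adjusted p = 0.613 with an estimated correlation). The called member was CENPN (-0.66), and 3 fell adjusted over the list alone: CENPN and NCAPD3 (-0.54), both known for chromosome segregation, and the prostaglandin dehydrogenase HPGD (-0.94). NCAPD3 and HPGD were picked after their values were seen. Without CENPN and NCAPD3, an alternative added after seeing the data, the median was -0.17 and the list was no longer called by camera (adjusted p = 0.0969), but fry with the replicate block called it (adjusted p = 0.0118). The 11 androgen-repressed targets had a median of 0.59, with 10 positive values (camera adjusted p = 0.000122, and adjusted p = 0.278 with an estimated correlation). No member passed over all genes, and 2 passed adjusted over the list alone, CAMK2N1 (0.72) and the opioid receptor gene OPRK1 (1.06). In the fit with the replicate block 6 repressed targets rose, among them DDC (1.01), an enzyme of dopamine synthesis, while 6 induced targets fell and 1, MAF (0.47), rose. MAF was picked after its value was seen. The prostate-specific antigen gene KLK3 was at -0.23 ± 0.34 in LnCaP (adjusted p = 0.894).

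Lists of lipid synthesis genes were called lower in LnCaP. All 10 fatty acid synthesis genes had negative values, with a median of -0.26 (camera adjusted p = 0.000216, and adjusted p = 0.204 with an estimated correlation), and fry gave an adjusted p of 0.0268. FASN, the fatty acid synthase gene, fell by 0.65 (adjusted p = 0.0407), and 2 genes fell adjusted over the list alone, FASN and the desaturase gene FADS2 (-0.44), the latter picked after its value was seen. With the block 4 fell over all genes, adding FADS2, ELOVL6 (-0.46) and SCD (-0.29), also picked after their values were seen. Of 18 cholesterol synthesis genes, 15 had negative values, with a median of -0.33 (camera adjusted p = 0.00154, and adjusted p = 0.915 with an estimated correlation). None passed over all genes, 3 fell adjusted over the list alone, namely INSIG1 (-0.63), EBP (-0.68) and SQLE (-0.53), and 9 fell and 1, TM7SF2 (0.37), rose with the replicate block. TM7SF2 was picked after its value was seen. The 27 genes of the integrated stress response and the unfolded protein response had a median of 0.08 (camera adjusted p = 0.00154, and adjusted p = 0.558 with an estimated correlation). Its smallest p-values were those of CRELD2 (0.28) and CALR (0.25), and 0 members passed over all genes or adjusted over the list alone, while with the block DDIT3 rose (0.52). Besides G2/M and fatty acid synthesis, fry called no list in LnCaP. Its adjusted p was 0.0621 for G1/S and replication genes, 0.248 for androgen-induced and 0.216 for androgen-repressed targets, 0.653 for cholesterol synthesis and 0.248 for the stress response list. Fry with the replicate block called 6 lists in LnCaP, 5 for the average and 0 in 22RV1. In LnCaP these were G2/M (adjusted p = 0.0156), androgen-induced (0.00464) and androgen-repressed targets (0.0118), cholesterol synthesis (0.0328), fatty acid synthesis (0.0369) and neuroendocrine genes (0.0118), but not G1/S and replication genes (0.0685) or the stress response list (0.335).

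In 22RV1, limma called 0 genes for nicotine, with 633 at an unadjusted p under 0.05. The count was also 0 with the replicate block (smallest adjusted p = 0.0791, 1351 at an unadjusted p under 0.05), and 1 with array weights, without treated replicate 3 or without untreated replicate 2. If no gene changed, a share of 0.05 of the 11963 genes would be expected at an unadjusted p under 0.05, and 633 is close to that share. The smallest p-values belonged to genes that did not pass. H3C6 was at 0.57 ± 0.09 (SE, n = 3 per group, adjusted p = 0.460) and the protocadherin gene PCDH7 at -1.23 ± 0.21 (adjusted p = 0.460). PSPC1 was at 0.50, HLA-DQB1 at -0.72, ALDOC at 0.45, RSRP1 at 0.61, the decoy receptor gene TNFRSF10D at 0.55, ABAT at 0.56 and ADIRF at -0.74. LPAR2 was at 0.56, KCNMB2 at 0.74, the cathepsin gene CTSK at 0.62, NMB at -0.61, ATXN1 at 0.49, GSDMB at 0.46, PRSS8 at 0.44, S100PBP at 0.40, NOTCH2NLA at 0.41 and the splicing kinase gene CLK4 at 0.38.

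In 22RV1, 4 lists were called. All 30 G2/M genes had negative values, with a median of -0.29 (camera adjusted p = 3.50e-18, and adjusted p = 0.784 with an estimated correlation), among them CCNB1 (-0.48) and DLGAP5 (-0.52). Of 18 cholesterol synthesis genes, 17 had positive values, with a median of 0.26 (camera adjusted p = 2.40e-05, and adjusted p = 0.965 with an estimated correlation). SREBF2 (0.32) and SQLE (0.38) had the smallest p-values. This list call was lost without untreated replicate 2, where 3 lists were called in 22RV1, all lower. Of 32 nuclear genes of the mitochondrial respiratory chain, 30 had negative values, with a median of -0.10 (camera adjusted p = 9.95e-06, and adjusted p = 0.965 with an estimated correlation), and CYC1 was at -0.16. The G1/S and replication genes had a median of -0.14 (camera adjusted p = 0.00204, and adjusted p = 0.965 with an estimated correlation), with TK1 at -0.32. In same-numbered pairs 1, 2 and 3 their list mean shifted by -0.0017, 0.0052 and -0.48, so the shift came from the arrays numbered 3. No member of these 4 lists passed over all genes or adjusted over the list alone, and fry called 0 lists in 22RV1. ALDOC, a glycolytic aldolase gene, passed adjusted over the hypoxia and glycolysis list alone.

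**Figure D2:**
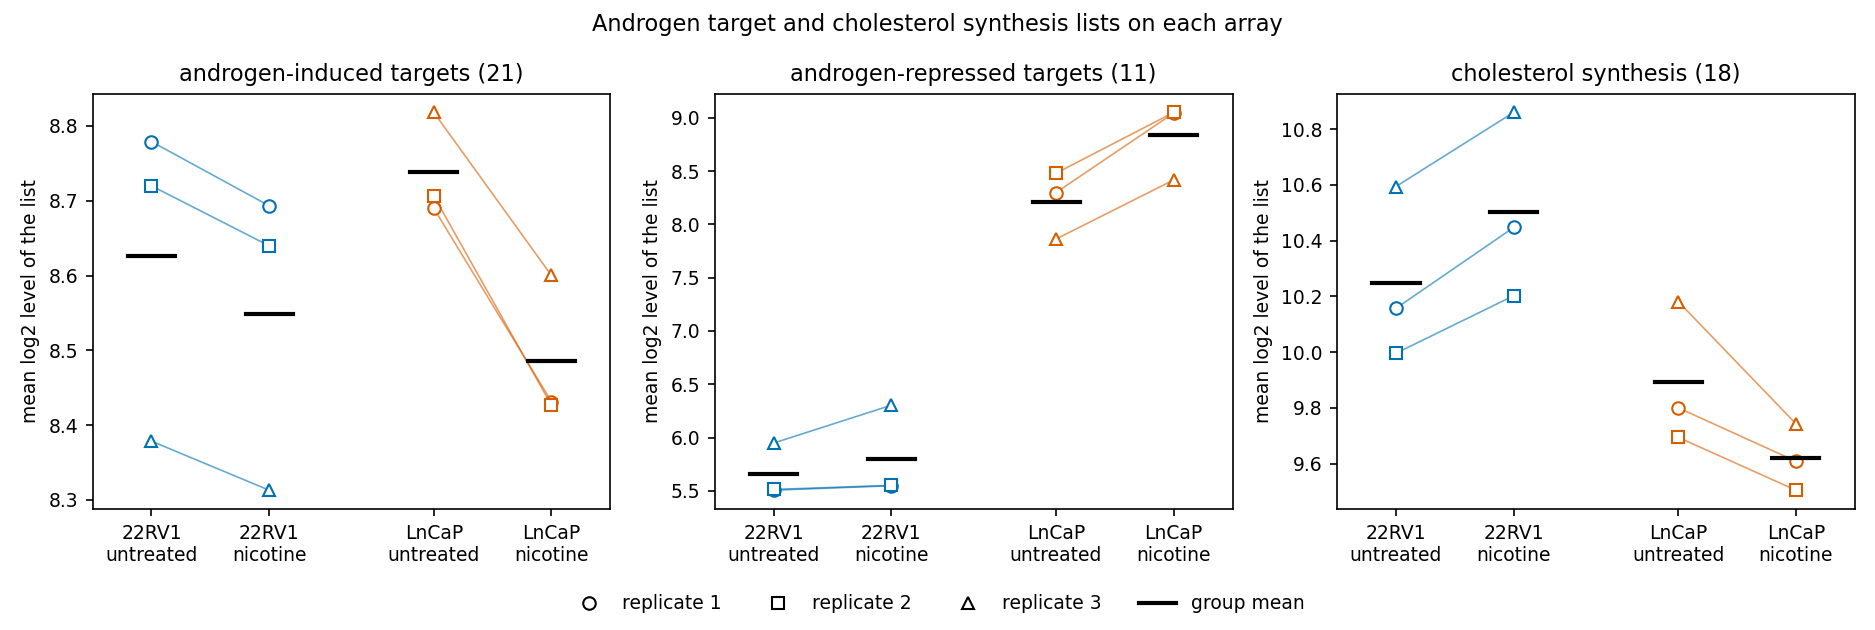
Mean log2 level of the androgen-induced (21 genes), androgen-repressed (11 genes) and cholesterol synthesis (18 genes) lists on each of the 12 arrays, with lines joining same-numbered arrays and black bars at group means. The cholesterol synthesis mean was 10.25 ± 0.31 and 10.50 ± 0.33 in untreated and treated 22RV1, and 9.89 ± 0.26 and 9.62 ± 0.12 in untreated and treated LnCaP (SD, n = 3).

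Averaged over both lines, 45 genes were called, of which 10 rose and 35 fell. PIMREG fell by 0.56 ± 0.07 (SE, n = 3 per group, adjusted p = 0.0144), KIF4A by 0.56 ± 0.08 (adjusted p = 0.0276) and CCNA2 by 0.53 ± 0.08 (adjusted p = 0.0301). H3C6 rose by 0.57 ± 0.07 (adjusted p = 0.0144) and CTSK by 0.58 ± 0.10 (adjusted p = 0.0356). Falls were also called for OIP5 (-0.59), CADPS2 (-0.58), RAD51AP1 (-0.55), BIRC5 (-0.52), TRIP13 (-0.51), SPAG5 (-0.49) and NCAPG (-0.49). Rises were also called for PLA2G2A (0.88), LARP6 (0.55), ATXN1 (0.50), TNFRSF10D (0.45), the splicing kinase genes CLK1 (0.43) and CLK4 (0.34), SHC2 (0.42) and FAM13A (0.41). PLA2G2A was at 0.07 in 22RV1 and 1.69 in LnCaP, so a called average need not be a change in both lines. Of the G2/M genes, 8 fell, 27 fell with the replicate block, and 30 fell adjusted over the list alone (median -0.46, camera adjusted p = 2.80e-38, and adjusted p = 0.124 with an estimated correlation). The G1/S and replication genes had a median of -0.40 with 23 lower adjusted over the list alone, 0 over all genes and 10 with the replicate block (camera adjusted p = 2.59e-19, and adjusted p = 0.519 with an estimated correlation). Androgen-repressed targets had a median of 0.37 (camera adjusted p = 0.000646, and adjusted p = 0.519 with an estimated correlation), and 0 passed, while 4 rose with the block, namely SI (0.92), OPRK1 (0.59), UGT2B17 (0.49) and DDC (0.38). DDC was at -0.25 in 22RV1 and 1.01 in LnCaP, so its average joins opposite directions. Androgen-induced targets had a median of -0.11 (camera adjusted p = 0.00948, and adjusted p = 0.828 with an estimated correlation), and CENPN fell (-0.49). With the block 4 fell, adding KLK2 (-0.69), NCAPD3 (-0.32) and KLK3, and of these members of both lists, KLK2, NCAPD3, UGT2B17 and DDC were picked after their values were seen. Without CENPN and NCAPD3 the induced list had a median of -0.095, a camera adjusted p of 0.115 and an adjusted p of 0.0204 by fry with the replicate block. KLK3 was at -0.31 ± 0.24 (adjusted p = 0.706), and in the fit with the block it fell (SE 0.066, adjusted p = 0.0430). Fatty acid synthesis genes had a median of -0.14 (camera adjusted p = 0.0411, and adjusted p = 0.613 with an estimated correlation), against 0.015 in 22RV1 and -0.26 in LnCaP. The respiratory chain genes had a median of -0.07 (camera adjusted p = 0.000850, and adjusted p = 0.891 with an estimated correlation), with CYC1 (-0.20) past the threshold adjusted over the list alone. The fit with the replicate block called 396 genes (153 higher and 243 lower), including all 45. Without the arrays numbered 3 the count was 7, and it was 0 without 22RV1 treated replicate 1, 22RV1 untreated replicate 3 or LnCaP treated replicate 2. In 22RV1 it was 3 without treated replicate 3 or untreated replicate 1, 7 without treated replicate 2 and 23 without untreated replicate 2. In LnCaP it was 9 without untreated replicate 1, 15 without untreated replicate 3, 22 without treated replicate 1 and 21 without treated replicate 3.

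The difference of the nicotine effect between the lines was tested for each gene, and limma called 0, with 749 at an unadjusted p under 0.05, and 1 without 22RV1 untreated replicate 2. DNAAF5 had the smallest p, with an effect lower in LnCaP by a log2 difference of -0.67 ± 0.10 (SE, adjusted p = 0.205). The next were CAPN15 (-0.87), LYRM9 (0.62), CFHR4 (0.73), ERBIN (0.58), B3GALT4 (0.79), PLA2G2A (1.62), MIPEP (1.03), FASN (-0.82) and DUSP2 (-0.46). In the fit with the replicate block 19 genes passed, 8 with a higher and 11 with a lower effect in LnCaP. They include PLA2G2A (1.62, adjusted p = 0.0333), DDC (1.26, adjusted p = 0.0333) and the sterol genes INSIG1 (-0.92, adjusted p = 0.0333), EBP (-0.85, adjusted p = 0.0426) and IDI1 (-0.68, adjusted p = 0.0432), of which all but PLA2G2A were picked after their values were seen. CAPN15 (adjusted p = 0.0426), DNAAF5 and B3GALT4 (0.0432 each) are also among them. Among the lists, 6 were called for the difference. The medians were -0.53 for G1/S and replication genes (camera adjusted p = 9.87e-12), -0.31 for G2/M genes (4.29e-11), -0.65 for cholesterol synthesis (1.66e-08) and -0.23 for fatty acid synthesis (0.000123). They were 0.091 for the stress response list (0.00508) and 0.45 for androgen-repressed targets (0.0158). With an estimated correlation the adjusted p was 0.652 for each of these but fatty acid synthesis, where it was 0.354. Adjusted over the list alone, 5 cholesterol synthesis genes (INSIG1, SQLE, MSMO1, EBP and SREBF2) and 2 fatty acid synthesis genes (FASN and FADS2) passed, all lower in LnCaP than in 22RV1 and, except FASN, named after their values were seen. The block also gave a call for the androgen-induced targets (median -0.17, camera adjusted p = 0.0259, and adjusted p = 0.397 with an estimated correlation).

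Across the 11963 genes, the log2 fold changes of the lines correlated with r = 0.231 and Spearman's rho = 0.196, and genes are not independent replicates. Of the 83 genes called in LnCaP, 73 had the same sign in 22RV1, including 65 of the 70 falls and 8 of the 13 rises. Their median was -0.61 in LnCaP and -0.15 in 22RV1. Without the arrays numbered 3, the correlation was 0.0976, and its jackknife SE over the 12 arrays was 0.125.

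**Figure D3:**
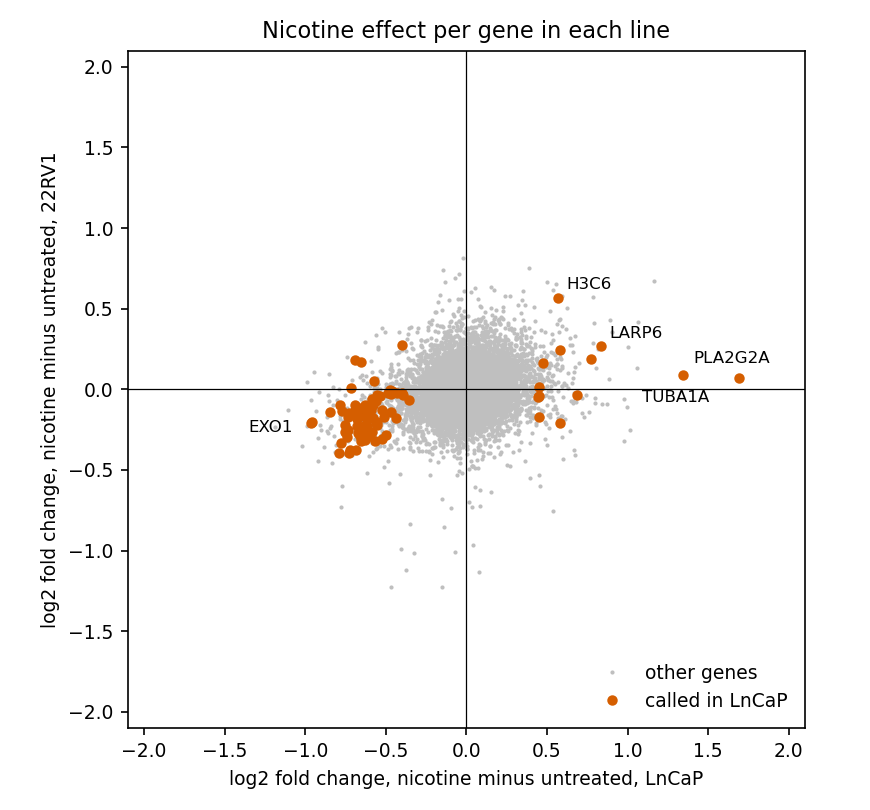
Log2 fold change after nicotine in LnCaP (horizontal axis) and in 22RV1 (vertical axis) for each of 11963 genes, with the 83 genes called in LnCaP in orange. Of these, 73 lie on the same side of 0 in both lines.

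The fixed lists of immunity and inflammation were not called after nicotine. The 29 genes of NF-kappaB cytokines and inflammation had medians of -0.0027 in 22RV1 and 0.012 in LnCaP (camera adjusted p = 0.933 and 0.577), and 0 passed over all genes. IL6 was at 0.05 ± 0.10 in 22RV1 and -0.13 ± 0.10 in LnCaP, and CXCL8 at 0.05 ± 0.10 and -0.0095 ± 0.096. CXCL8 levels ran from 3.92 to 4.33 over the arrays, below the array medians of 6.61 to 6.71. Signal over background was not tested, so the lack of a change in such dim genes says little. The 32 interferon-stimulated genes had a median of 0.03 and a mean of -0.01 in LnCaP (camera adjusted p = 0.973, and 0.882 in 22RV1), and the 17 genes of MHC and antigen processing gave 0.973 in LnCaP and 0.956 in 22RV1. Marker lists of other cell types were not called in either line, and the adjusted p in LnCaP was 0.973 for B-lineage, T and NK cell, myeloid, and fibroblast and endothelial markers. Their levels were low as well, with list means in untreated LnCaP of 4.79 for T and NK cell and 4.70 for myeloid markers. Single genes passed adjusted over their list alone in LnCaP, namely the interferon-stimulated OAS3 (-0.57) and the endothelial marker VWF (0.56). In the fit with the block OAS3 fell (adjusted p = 0.0185), HLA-E rose (0.43, adjusted p = 0.0112) and the fibroblast marker ACTA2, picked after its value was seen, fell (-0.99, adjusted p = 0.0115) over all genes, while VWF did not pass (0.0520). The 14 nicotinic receptor subunits had a median of 0.0021 in LnCaP and -0.026 in 22RV1 (adjusted p = 0.973 and 0.723). The subunit gene CHRNA5 was at -0.33 ± 0.12 in LnCaP (adjusted p = 0.232) and -0.00073 ± 0.116 in 22RV1. Nicotine-metabolising enzymes (0.973 in LnCaP) and aryl hydrocarbon receptor targets (0.973) were not called either, and CYP1A1 was at -0.14 ± 0.22 in LnCaP and -0.42 ± 0.22 in 22RV1.

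The remaining lists were not called for nicotine in LnCaP. The camera adjusted p was 0.973 for the BCL2 family, cAMP and CREB targets, heat shock genes, mesenchymal transition genes and p53 targets. It was 0.577 for epithelial genes, hypoxia and glycolysis genes, ribosomal proteins and neuroendocrine genes, 0.728 for immediate early genes, 0.708 for NRF2 oxidative stress genes, 0.536 for replication-dependent histones and 0.509 for respiratory chain genes. SPARC (-0.67), a matrix protein gene of the mesenchymal list, passed adjusted over that list alone, and over all genes with the block (adjusted p = 0.0196). With the replicate block the neuroendocrine list was called (0.0474, and 0.422 with an estimated correlation), and 4 of its 15 genes rose: DDC (1.01), NTS (0.80), ENO2 (0.45) and SYT1 (0.43). DDC and NTS are also in the androgen-repressed list. Median, mean and test direction differed in sign in LnCaP for the interferon, nicotinic receptor, p53, B-lineage and mesenchymal lists. In 22RV1 they did so for the interferon, inflammation, epithelial, hypoxia, fibroblast and endothelial, B-lineage, neuroendocrine and histone lists. None of these was called.

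The untreated lines differed widely, with 5719 genes called, 3042 higher and 2677 lower in LnCaP. LnCaP was higher in the chemokine receptor gene ACKR3 (6.28 ± 0.32, SE, n = 3 per group, adjusted p = 1.35e-08), RAB25 (5.92), the steroid-conjugating enzyme gene UGT2B17 (5.74), the zinc transporter gene SLC30A4 (5.71), PEG3 (5.67) and ALDH1A3 (5.31). It was lower in the trypsin inhibitor gene SPINK1 (-7.66 ± 0.47, adjusted p = 7.28e-08), the connexin gene GJA1 (-7.54), the albumin gene ALB (-7.27), PEG10 (-7.06), TSPAN8 (-6.76) and the galectin gene LGALS1 (-6.61). Mean levels on the lower side ran from 3.28 for GJA1 in LnCaP to 6.19 for PEG3 in 22RV1, and signal over background was not tested. KLK3 was higher in LnCaP by 4.09 ± 0.34 (adjusted p = 1.02e-06) and CYP1A1 was lower (-0.91, adjusted p = 0.00373).

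Of 30 lists, 10 were called between the untreated lines. Replication-dependent histones were higher in LnCaP, with 19 of 26 called (median 0.51, camera adjusted p = 1.28e-05), and this call alone held with an estimated correlation (adjusted p = 0.0144). H4C8 (4.87) and H2BC5 (3.14) were examples, and the list members named for this comparison were picked after their values were seen. Androgen-repressed targets (median 2.36, adjusted p = 0.00711, and 0.413 with an estimated correlation), p53 targets (0.47, 0.00658, and 0.376), genes of MHC and antigen processing (0.56, 0.00658, and 0.463) and hypoxia and glycolysis genes (0.50, 0.0158, and 0.218) were also higher. HLA-B was higher by 2.58 and GDF15 by 4.06. Genes of G2/M (-0.44, 3.14e-05, and 0.482), G1/S and replication (-0.69, 8.29e-05, and 0.646), the immediate early response (-0.47, 0.00658, and 0.376), the neuroendocrine type (-0.40, 0.0205, and 0.218) and cAMP and CREB (-0.51, 0.0208, and 0.287) were lower. Without 22RV1 untreated replicate 1, where FOS was at 8.79 against 5.90 and 5.58 on the other untreated 22RV1 arrays, the immediate early list had a median of -0.26 and was still called (adjusted p = 0.0180). FOS was picked after its values were seen. The neuroendocrine list was still called with any of the untreated arrays left out, but its median then ran from -0.61 to -0.26. EGR1 was at -2.69, SCG3 at -4.29 and RGS2 at -6.15. Among nicotinic receptor subunits, CHRNB1 (-1.72), CHRNA2 (-1.25) and CHRNE (-0.65) were lower in LnCaP, and the list was not called (adjusted p = 0.327).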

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

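The range tests of untreated cultures were assigned to single lists, and the covariate was joined with the replicate block, after the shifts had been seen, whereas the other tests of these patterns were written before their results. Camera called lists for the difference of the nicotine effect between the lines. The median difference, LnCaP minus 22RV1, was -0.53 for G1/S and replication genes, -0.31 for G2/M genes, -0.65 for cholesterol synthesis, -0.23 for fatty acid synthesis, 0.091 for the integrated stress and unfolded protein response and 0.45 for androgen-repressed targets. None of these calls held with an estimated correlation. By exact permutation of the pairs between the lines, p was 0.2 for G1/S and replication genes and for the stress response list. It was 0.1, the smallest possible, for the others. In the fit with the replicate block, 19 genes passed for the difference, against 0 without it. Outside the gene table, 8 probe sets without a single gene symbol were called for nicotine in LnCaP.

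Camera called the G2/M and G1/S lists lower after nicotine in LnCaP, where 10 of 30 and 1 of 28 genes passed, but not with an estimated correlation (adjusted p = 0.155 and 0.278), while fry called G2/M (0.00755, and 0.0156 with the block) and not G1/S (0.0621 and 0.0685). With the 3-prime minus 5-prime difference of actin and GAPDH as a covariate, the shifts kept 0.972 and 1.07 of their size. The 95% intervals were -0.85 to -0.32 and -1.10 to -0.29, and with the replicate block added -0.85 to -0.28 and -1.28 to -0.07. The covariate ran from -0.065 to 0.056 on untreated and from -0.055 to 0.023 on treated LnCaP arrays. With such an overlap it could hardly take up the shifts. The test argues only against a difference of RNA integrity that these probe sets register, and labelling differences that they miss stay open. Both medians lay at percentile 0 of 10000 random lists matched on mean level, which argues against a shift that depends on intensity. The range among untreated LnCaP arrays was 0.309 of the G2/M shift, and each pair shifted by more than that range, whereas for G1/S genes it was 0.897 of the shift. Since replicates may be technical, this range may not measure differences between cultures, which stay open for both lists. A lower proliferation of LnCaP in nicotine stays a candidate explanation for the G2/M genes, as a hypothesis only, since growth was not measured here, and cell counts or cell cycle profiles beside a tartrate control would be needed to decide it.

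Camera called the cholesterol synthesis list higher after nicotine in 22RV1 and lower in LnCaP, in 3 of 3 pairs each, but 0 of 18 genes passed in either line, neither call held with an estimated correlation (adjusted p = 0.965 and 0.915) or with fry (0.977 and 0.653), and fry with the block called the list in LnCaP (0.0328) and not in 22RV1 (0.0944). Without 22RV1 untreated replicate 2 the call in 22RV1 was lost. With the covariate the shifts kept 0.840 and 1.16 of their size, with 95% intervals that included 0 (-0.31 to 0.73 and -0.84 to 0.20). By the test as first written, RNA integrity or labelling therefore stays open. With the replicate block added, after the shifts had been seen, the intervals excluded 0 (0.02 to 0.47 and -0.51 to -0.05), on 3 residual degrees of freedom. The medians lay at percentiles 100 and 0 of matched random lists, which argues against a shift by intensity. The range of the list mean among untreated arrays was 2.35 times the shift in 22RV1 and 1.78 times in LnCaP. By the test as first written, this is the outcome that differences between cultures would give. That test did not weigh the pairs, which remove differences across replicate numbers where the pairing holds. Differences between cultures therefore stay open. The opposite direction in the lines had an exact permutation p of 0.1, the smallest possible with 3 pairs per line.

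Camera called androgen-induced targets lower, though not without CENPN and NCAPD3 (adjusted p = 0.0969), and androgen-repressed targets higher after nicotine in LnCaP, where 1 of 21 and 0 of 11 passed, neither call held with an estimated correlation (0.613 and 0.278) or fry (0.248 and 0.216), and fry with the block called both lists (0.00464 and 0.0118). With the covariate the shifts kept 1.08 and 1.13 of their size. The 95% interval included 0 for the induced list (-0.60 to 0.05), so RNA integrity or labelling stays open there. It excluded 0 for the repressed list (0.10 to 1.31). As the covariate overlapped between the LnCaP groups, this argues only against a difference of RNA integrity that it registers. Labelling differences that it misses stay open for that list too. With the replicate block added, after the shifts had been seen, both intervals excluded 0 (-0.29 to -0.20 and 0.32 to 0.95), on 3 residual degrees of freedom. The medians lay at percentiles 0 and 100 of matched random lists, which argues against a shift by intensity. The range among untreated arrays was 0.509 of the shift for induced targets, with each pair beyond it, and 0.990 for repressed targets. Since replicates may be technical, this range may not measure differences between cultures, which stay open for both lists.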

How the results depend on the processing

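The fits without the arrays numbered 3, the block joined with an estimated correlation or with fry, and the androgen-induced list without CENPN and NCAPD3 were chosen after seeing the data. Counts of called genes depended on the arrays used. Leaving out an array gave 0 to 108 genes in LnCaP, 0 to 36 for the average, 0 to 1 in 22RV1 and 0 to 1 for the difference. LnCaP had 0 without treated replicate 2 or untreated replicate 3, 2 without untreated replicate 1 and 27 without treated replicate 1. The average had 0 without 22RV1 treated replicate 1, 22RV1 untreated replicate 3 or LnCaP treated replicate 2, and 3 without 22RV1 treated replicate 3 or untreated replicate 1. It had 7 without 22RV1 treated replicate 2, 9, 15, 22 and 21 without LnCaP untreated replicates 1 and 3 and treated replicates 1 and 3, and 23 without 22RV1 untreated replicate 2. Without 22RV1 treated replicate 3 or untreated replicate 2, 22RV1 had 1 gene, and without the latter the difference had 1. The replicate block raised the counts to 645 in LnCaP, 396 for the average and 19 for the difference, and added the neuroendocrine list in LnCaP and the androgen-induced list for the difference. With the block 19 results for named genes gained a call and 0 lost it, and the other camera list calls for nicotine did not change. Array weights gave 1 in 22RV1, 175 in LnCaP and 112 for the average. Leaving out dim genes, with fewer genes tested, gave 135 and 70, and the trended variance model gave 132 in LnCaP. The fit of 6 arrays gave 1 in LnCaP, which was higher, with fewer samples. All probe sets gave 9729 between the untreated lines, with more features tested. Without the arrays numbered 3 the counts were 143 in LnCaP and 7 for the average, and the correlation was 0.0976. Apart from fewer or more features or arrays, the cause was not tested. List calls in 22RV1, LnCaP and the average numbered 4, 7 and 6; with an estimated correlation they were 0 in each, with or without the replicate block, with fry 0, 2 and 1, and with fry and the block 0, 6 and 5. For the difference fry gave 0, and 3 with the block. Leaving out an array gave 3 to 5 list calls by camera in 22RV1, 6 to 7 in LnCaP and 4 to 7 for the average. Without 22RV1 untreated replicate 2, 0 lists were called higher in 22RV1, so the cholesterol synthesis call was lost. Of 160 results for named genes, 7 lost their call with quantile normalization, and 31 lost and 7 gained it without the arrays numbered 3. Over all fits that leave out an array, 383 such results lost and 4 gained a call. Signs turned for genes that were not called: leaving out an array gave -0.079 to 0.062 for CHRNA5, -0.034 to 0.133 for IL6 and -0.74 to 0.039 for KLK3 in 22RV1, and -0.11 to 0.075 for CXCL8 in LnCaP. CHRNA5 in 22RV1 was at 0.098 without the arrays numbered 3. Signal over background was not used here, and the number of arrays limits the precision.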

Other observations

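The correlation over splits that part all pairs was tested after the other splits had been seen. Genes outside the fixed lists, chosen after their values were seen, moved in LnCaP in the fit with the replicate block. The prostatic acid phosphatase gene ACP3 was at 1.07 (adjusted p = 0.00435), the cholinesterase gene BCHE at 1.00 (0.0110), the adrenoceptor gene ADRA2A at 0.98 (0.00871), the microtubule protein gene MAP1B at 0.90 (0.00435) and TFF3 at 0.87 (0.0159). The prostate secretory genes AZGP1 (-0.71, 0.00435) and MSMB (-0.60, 0.00696) were lower. Of the replication genes outside the list, MCM10 was at -1.19 (0.0123), ORC1 at -0.92 (0.0108) and POLE2 at -0.87 (0.00885). Without the block none of these passed, and the smallest adjusted p among them was 0.0529, for AZGP1.

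Other splits of the arrays were fitted as the real split was. The 10 splits of 6 arrays are too few for a share under 0.05. In LnCaP the real split gave 83 genes and the highest other 2, with 7 lists against 7. In 22RV1 it gave 0 genes against 1, and 4 lists against 8. Between the untreated lines it gave 5719 genes against 0. For the average, 1 of 100 drawn splits, the real split, gave as many as 45 genes (highest other 2). For lists, 20 of 100 gave 6 or more (highest 9). The drawn splits could leave same-numbered arrays on the same side, though these were taken as pairs. Among the 32 splits that part all 6 pairs, with the block, 1 gave 396 genes or more (highest other 35). Without the block, 7 of these gave 6 lists or more (highest other 7). Gene counts of the average thus stood beyond those of other splits of these arrays, and for list counts chance cannot be excluded. Since replicates may be technical, such splits cannot exclude a chance difference between treated and untreated cultures. For the difference all 100 gave 0 genes or more; the highest other, 45, is the split that swaps the labels within a line and so turns the difference into the average. A correlation between the lines of 0.231 or more was given by 2 of 100 splits (highest other 0.253), a share under 0.05. It was also given by 2 of the 32 splits that part all 6 pairs (highest other 0.247), a share above 0.05. For the correlation chance therefore cannot be excluded. The jackknife SE over arrays was 0.125, and the correlation was 0.0976 without the arrays numbered 3.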
